A study of Mus musculus with 128 samples.

How the data were processed

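The libraries were made from single neurons of Phox2b::GFP mice (line Jx99), in which green fluorescent protein marks neurons that express the transcription factor Phox2b. Per the labels, fluorescent cells were drawn into a micropipette from brainstem slices, and polyadenylated RNA was amplified and sequenced after Nextera XT library preparation. The table deposited by the authors holds TPM (transcript abundance scaled to the same total in every library) per gene and cell. Per the submitters' processing notes, the TPM were made with Salmon against the mouse genome build GRCm38. The Salmon version, the index and the way transcripts were summed to genes are not given in the sources used here. TPM carry no read depth, so the depth per cell is unknown and the number of genes at TPM of at least 1 served as the measure of library complexity. The TPM of each library summed to between 996034 and 999767 over the genes in the table.

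The table had 31679 rows, of which 31278 matched a gene ID in the symbol table and 401 did not. Rows that shared a symbol were summed, which concerned 133 symbols, and 26 symbols that a spreadsheet had turned into dates were restored from their IDs, leaving 31544 symbols. Xist, Tsix and Galr3 are not in the table. No column belonged to a library without a label and no 2 libraries held identical values. The highest Pearson correlation between a pair of libraries was 0.935 on the log2 scale. Of 128 libraries, 115 were clean single cells. Left out of the main comparisons were 10 cells labelled GAD contaminated, 2 pooled libraries and 1 cell labelled as bad data. The contaminated RTN cells entered a comparison of their own, and the other excluded libraries are described as values.

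Cell types were those of the labels: RTN neuron, C1 neuron, P2b neuron and RTN_d. How cells received a type is not stated, so the markers of a type may have defined it and are then not independent evidence. The letter d in RTN_d is not explained either. Cells of 1 animal are not replicates, so the replicate was the harvest set, meaning all cells with the same batch, age and genotype, 16 sets in all. The labels name no animals. A mouse is harvested once, so sets that differ in age or genotype came from different mice. Sets of the same age in 2 batches (P11 in batches 2 and 5, P13 in batches 1 and 5) may not be separate animals, and an alternative merged them. Where types or labels were compared within sets, the p-values measure how much the within-set differences vary from set to set. For age and genotype they measure the spread between sets within batches. Both include the spread between cells, as many sets hold 1 cell of a type. The 9 C1 cells came from 5 sets, the 10 P2b cells from 4 and the 5 RTN_d cells from 4. The 7 contaminated RTN cells came from 7 sets, and some wild-type RTN sets hold 1 cell. Of 15 sets with at least 2 clean cells, 6 held cells with and without RNA of Y-linked genes at TPM of 10, so these may combine several animals.

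For each set and type, the mean over cells of log2(TPM + 1) was taken, with a pseudocount of 1. Genes with a mean of at least 1 over the profiles in a fit were kept. Linear models were fitted with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, with two-sided tests and a Benjamini-Hochberg threshold of 0.05. C1, P2b and RTN_d neurons were compared with RTN neurons in 1 model with the harvest set as a block, over 22 profiles of 9 sets and 11027 genes. Pairs are therefore profiles of 2 types from 1 harvest set: 5 for C1, 4 for P2b and 4 for RTN_d. These 3 comparisons share control profiles and are not independent of each other. Adult and young wild-type RTN neurons were compared with batch as a term (11267 genes), and Gpr4-null and wild-type RTN neurons with batch and stage as terms (11310 genes). Contaminated and clean RTN cells were compared in 7 sets with the set as a block (11476 genes). Log2 differences are on the scale of log2(TPM + 1), which understates changes of genes with low values. Exact permutation and sign-flip tests of sets were two-sided. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

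The comparisons, alternatives and 32 gene lists were fixed before the data were examined. The lists were RTN markers, adrenergic C1 markers, GABA and glycine markers, vesicular glutamate transporters, cholinergic and motor neuron markers, serotonergic markers, neuropeptides, proton and CO2 sensing candidates, K2P potassium channels, serotonin receptors, other aminergic and acetylcholine receptors, and peptide, opioid and purine receptors. Further lists held pacemaking and excitability channels, hindbrain transcription factors, HOX genes, immature neuron genes, mature neuron genes, perineuronal net genes, synaptic vesicle genes, MHC class I and interferon response genes, and markers of astrocytes, oligodendrocytes, oligodendrocyte precursors (OPC), microglia, vascular cells and red blood cells. The last were immediate early and stress genes, sex-linked check genes, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, and proteasome genes. Each list was compared with all other genes by camera, with the preset correlation between genes of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Counts of members past the threshold are given over all genes and adjusted over the list alone.

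Genes are named by a rule. In the genotype comparison, Gpr4 and Kcnk5 are named. In each comparison, the 8 largest positive and 8 largest negative differences are taken from genes past the threshold that differed the same way in every pair, or in every batch for age, with Gm and Rik gene models and pseudogenes left out. Up to 4 members per list with the smallest adjusted p are taken, or up to 2 where none passed. Markers of RTN, C1 and GABA neurons can always be named. In the description, up to 6 members per list found in the largest share of cells are taken, with members found in few or no cells where these matter. The text shortens these selections to the genes with the clearest background.

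The alternatives were pseudocounts of 0.1 and 10, no filter or a stricter filter of 2, the log2 of the mean TPM, upper-quartile scaling, weights by number of cells, no block or no batch term, only the 2 types compared, wild-type sets only, merged ages, sets with at least 2 cells, contaminated cells included, and each set left out in turn. Genes detected were also counted at TPM above 0 and at TPM of at least 10. After seeing the data, 2 alternatives were added: cells with fewer than 7000 genes detected left out, and the mean number of genes detected as a covariate. Also chosen after seeing the data were permutations of stage within batches for genes detected, with 2 weightings of the batches, the relation of Nmb to Gal in wild-type sets only, GABA and glycine markers with the labelled cells put back, and list medians of null against wild-type sets within batch 4 by age. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only.

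The models were tested on simulated data made from the design of each comparison with 200 changed genes. Of genes with a made difference of 8 on the log2 scale, 100% were recovered in every design. At a difference of 4, recovery was 82.8% for C1, 64.4% for P2b, 74.4% for RTN_d, 72.5% for age, 40.8% for genotype and 90.9% for contamination. At a difference of 2 it was 18.4%, 13.2%, 10.9%, 22.9%, 4.2% and 33.3% in the same order, so small differences are mostly out of reach. False calls were 8 of 118, 3 of 85, 5 of 87, 4 of 105, 1 of 80 and 6 of 124. The simulated noise was normal, independent between genes and of 1 size per gene in all profiles, drawn once per design. Recovery and false calls hold for such noise alone. Real profiles differ in cells and complexity, and another split of the contaminated and clean profiles gave 467 genes.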

Results

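The retrotrapezoid nucleus (RTN) is a group of excitatory brainstem neurons that senses CO2 and protons and drives breathing. The transcriptomes of single fluorescent neurons were measured as TPM, to describe the transcripts of RTN neurons and to set them beside other Phox2b-expressing neurons of the same batches. Of 115 clean single cells, 91 were RTN neurons, 9 were C1 neurons, 10 were P2b neurons and 5 were RTN_d neurons. Among the RTN neurons, 73 were wild type from 13 harvest sets, 9 lacked Gpr4, and 9 came from double knockouts of Gpr4 and Kcnk5. Ages ran from postnatal day 5 (P5) to P118 over 5 batches. The number of genes at TPM of at least 1 per library ran from 4763 to 13377, with a median of 10160 in clean cells. Mitochondrially encoded genes took a median of 3.73% of the TPM of a clean cell and at most 25.69%.

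The description asked which transcripts wild-type RTN neurons hold. Nmb, which encodes the peptide neuromedin B, was found at TPM of at least 1 in all 73 cells (95% interval 95.1% to 100%), with a mean of 7080 ± 4560 TPM (SD, n = 13 sets). Phox2b at 395 ± 140 TPM, Slc17a6, the vesicular glutamate transporter VGLUT2, at 169 ± 22.2 TPM, and Adcyap1, which encodes the peptide PACAP, at 459 ± 265 TPM were also found in all 73 cells. Atoh1, a transcription factor of hindbrain development, was found in 98.6% of cells (92.6% to 100%), and Penk, the enkephalin precursor, in 95.9% (88.5% to 99.1%). Of the proposed proton detectors, the receptor gene Gpr4 was found in 67 cells, or 91.8% (83.0% to 96.9%), at 164 ± 142 TPM. Kcnk5, which encodes the K2P channel TASK-2, was found in 58 cells, or 79.5% (68.4% to 88.0%), at 24.6 ± 23.4 TPM. Gal, the galanin precursor, was found in 62 of the 73 cells. In all, 9734 genes were found in at least 50% of wild-type RTN cells. All 10 RTN markers were among them.

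On GRCm38, Nmb (ENSMUSG00000025723) lies on chromosome 7 at 80902227 to 80905076, Gpr4 on chromosome 7 at 19212538 to 19224174 and Kcnk5 on chromosome 14 at 20140057 to 20181809. Gal lies on chromosome 19 at 3409915 to 3414544, Phox2b on chromosome 5 at 67094399 to 67099301, Adcyap1 (ENSMUSG00000024256) on chromosome 17 at 93199017 to 93206537 and Atoh1 (ENSMUSG00000073043) on chromosome 6 at 64729125 to 64731245. Of the C1 markers, Th lies on chromosome 7 at 142892752 to 142931128, Dbh on chromosome 2 at 27165233 to 27183200, Pnmt on chromosome 11 at 98386450 to 98388181 and Cartpt on chromosome 13 at 99898489 to 99901091. The GABA-synthesis gene Gad1 lies on chromosome 2 at 70553072 to 70602014.

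Catecholamine genes were found in part in RTN neurons. Of 11 adrenergic C1 markers, 4 were in at least 50% of the cells: Phox2a in 98.6%, the amine-degrading enzyme Maoa in 93.2% (84.7% to 97.7%), the decarboxylase Ddc in 90.4% (81.2% to 96.1%) and the vesicular transporter Slc18a2 in 64.4%. The rate-limiting enzyme Th was found in 6 of 73 cells, Dbh in 7, and Pnmt, which makes adrenaline, in 0. Of 10 GABA and glycine markers, 2 were in at least 50% of the cells, the GABA transporter Slc6a1 in 91.8% and Gad1 in 52.1% (40.0% to 63.9%) at 3.41 ± 2.79 TPM. These values leave out 7 wild-type RTN cells labelled GAD contaminated, and with them the sets held Gad1 at 16 ± 27.2 TPM. Gad2 was found in 23.3% of cells and the vesicular GABA transporter Slc32a1 in 28.8%. Of 3 vesicular glutamate transporters only Slc17a6 was in most cells, with Slc17a7 in 26.0% and Slc17a8 in 2.7% (0.3% to 9.5%). Of 8 cholinergic and motor neuron markers only the intermediate filament gene Prph was in most cells (89.0%, 190 ± 164 TPM). None of the 4 serotonergic markers was, with Tph2 and the serotonin transporter Slc6a4 each in 8.2% (3.1% to 17.0%).

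RTN neurons held a broad set of peptide, receptor and channel transcripts. Of 32 neuropeptide genes, 9 were in at least 50% of the cells, among them the granin genes Scg2 at 653 ± 345 TPM and Chga at 486 ± 242 TPM, both in 100%. Of 18 proton and CO2 sensing candidates, 6 were, with the carbonic anhydrase Car2 at 179 ± 93.2 TPM in 100% and the acid-sensing channels Asic1 in 93.2% and Asic2 in 84.9%. Of 14 K2P potassium channels, 4 were, with Kcnk1 in 97.3% and Kcnk2 in 82.2%. Of 14 serotonin receptors, 2 were: Htr2c in 100% at 56.0 ± 30.2 TPM and Htr1b in 60.3%. Among other aminergic and acetylcholine receptors 5 of 27 were, including the adrenergic receptor Adra1b in 78.1% and the nicotinic subunit Chrna7 in 65.8%. Among peptide, opioid and purine receptors 11 of 39 were, including the nociceptin receptor Oprl1 in 93.2%, the adenosine receptor Adora1 in 90.4% and the orexin receptor Hcrtr2 in 82.2%. Of 44 pacemaking and excitability channels, 28 were, with Scn1b at 174 ± 79.6 TPM in 100%, Kcnq2 in 98.6% and Hcn2 in 97.3%. Of 30 hindbrain transcription factors, 9 were, with Meis1 in 87.7% and Lbx1 in 84.9%. Of 39 HOX genes, 2 were, Hoxb3 in 87.7% and Hoxb2 in 79.5%, and 21 were found in no cell.

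Genes of both early and late neuronal stages were found, as 24 of 26 immature neuron genes, 20 of 25 mature neuron genes and 18 of 21 synaptic vesicle genes were in at least 50% of the cells. The tubulin Tuba1a stood at 2910 ± 1040 TPM and the vesicle fusion gene Snap25 at 2200 ± 995 TPM. Of 8 perineuronal net genes 2 were, Bcan and Ncan, each in 54.8%. Of 16 MHC class I and interferon response genes 7 were, with B2m at 169 ± 101 TPM. The immediate early gene Fos stood at 284 ± 167 TPM in 97.3% of cells, and 12 of the 16 immediate early and stress genes were in at least 50%. Markers of other cells were found too. The members in the largest share of cells were Mbp of oligodendrocytes at 2060 ± 1700 TPM in 98.6%, Aldoc of astrocytes at 1030 ± 556 TPM in 100%, and Hexb of microglia at 93.2 ± 77.3 TPM in 95.9%. Other members were much lower, such as the astrocyte genes Aqp4 (2.79 TPM, 41.1%), Gja1 (1.47 TPM, 31.5%) and Aldh1l1 (1.19 TPM, 23.3%). The microglia gene Csf1r was at 6.37 TPM in 32.9%. Aldoc was also found in all 6 C1, 10 P2b and 5 RTN_d wild-type cells. Whether these transcripts came from other cells was not tested here. In at least 50% of the cells were 9 of 12 oligodendrocyte, 7 of 11 astrocyte, 8 of 11 microglia, 0 of 5 OPC, 1 of 11 vascular and 2 of 5 red blood cell genes. The haemoglobin gene Hba-a2 was in 67.1% of cells. Of the lists for general cell functions, 73 of 78 cytosolic ribosomal proteins, 13 of 13 mitochondrially encoded genes, 70 of 76 nuclear oxidative phosphorylation genes, 35 of 39 proteasome genes and 2 of 4 sex-linked check genes were in at least 50% of the cells.

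C1 neurons are the adrenergic neurons of the ventrolateral medulla, next to the RTN, and this comparison asked how they differ from RTN neurons. The 5 sets were not all wild type, as they included the P94 double knockout and the P16 Gpr4 knockout. In C1 neurons the catecholamine enzymes Th, Dbh and Pnmt and the peptide precursor Cartpt stood far above their level in RTN neurons of the same sets, and Nmb far below. Cartpt, the precursor of the CART peptide, was at 5796 ± 1129 TPM in C1 against 1.84 ± 2.08 in RTN neurons (SD, n = 5 sets each), and Nmb at 3.31 ± 4.53 against 8241 ± 2954 TPM. Acetylcholine genes were higher in C1 neurons, while the serotonin receptor gene Htr2c and the peptide genes Gal and Adcyap1 were lower. In limma, 132 genes passed the threshold, 48 higher and 84 lower in C1 neurons, of which 116 differed the same way in all 5 pairs. The median log2 difference of all 11027 genes was -0.60, and C1 libraries held 7722 ± 2415 genes detected against 9377 ± 956 in RTN neurons (exact sign-flip p = 0.312, n = 5 pairs, smallest possible 0.0625).

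Of 10 adrenergic C1 markers tested, 6 were higher in C1 neurons over all genes and 7 adjusted over the list alone (camera adjusted p = 2.48e-29, and adjusted p = 6.5e-05 with an estimated correlation). Cartpt was higher by 11.68 ± 0.87 on the log2 scale (SE, adjusted p = 5.1e-08, 5 of 5 pairs). Dbh, which makes noradrenaline, was at 609 ± 314 against 0.0218 ± 0.0300 TPM, a log2 difference of 9.00 ± 0.67 (adjusted p = 5.1e-08, 5 of 5 pairs). Th was at 1308 ± 418 against 7.5 ± 9.18 TPM, a log2 difference of 8.72 ± 0.78 (adjusted p = 7.88e-07, 5 of 5 pairs). Pnmt was at 431 ± 141 against 0.0723 ± 0.109 TPM, a log2 difference of 8.45 ± 0.69 (adjusted p = 2.08e-07, 5 of 5 pairs). Maoa (log2 difference 5.02 ± 0.69, adjusted p = 0.000307, 5 of 5 pairs) and Gch1, which makes the cofactor of Th (4.00 ± 0.80, adjusted p = 0.0126, 4 of 5 pairs), were the other members. Ddc (log2 difference 3.39, adjusted p = 0.0813, 5 of 5 pairs) and Slc18a2 (-0.14, adjusted p = 0.962, 2 of 5 pairs) did not pass the threshold over all genes. All 6 wild-type C1 cells held Th, Dbh, Pnmt and Cartpt.

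Of 10 RTN markers, 5 were lower in C1 neurons over all genes and 8 adjusted over the list alone (camera adjusted p = 3.34e-12, and adjusted p = 0.00198 with an estimated correlation). Nmb was lower with a log2 difference of -11.42 ± 0.53 (adjusted p = 1.64e-11, 5 of 5 pairs). Gal (log2 difference -6.62 ± 1.45, adjusted p = 0.0225, 4 of 5 pairs) and Adcyap1 (-3.90 ± 0.94, adjusted p = 0.0437, 5 of 5 pairs) were lower too. Atoh1 was listed at 0 in C1 neurons against 92.3 ± 49 TPM in RTN neurons (adjusted p = 0.000765, 5 of 5 pairs), and Kcnk5 at 0 against 12.5 ± 6.00 TPM (adjusted p = 0.0228, 5 of 5 pairs). The RTN mean of Kcnk5 included the double-knockout set, at 3.75 TPM. Gpr4 had a log2 difference of -3.95 ± 1.08 (adjusted p = 0.0844, 5 of 5 pairs) in a comparison whose RTN sets included Gpr4-null ones. Tacr1, the substance P receptor, had a log2 difference of -3.41 (adjusted p = 0.0998, 5 of 5 pairs). Phox2b (log2 difference -0.91 ± 0.34, adjusted p = 0.248, 4 of 5 pairs), Slc17a6 (-0.93, adjusted p = 0.436, 3 of 5 pairs) and Penk (-1.65, adjusted p = 0.558, 4 of 5 pairs) did not pass either.

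Of 5 cholinergic and motor neuron markers, 3 were higher over all genes (camera adjusted p = 1.71e-05, and adjusted p = 0.00821 with an estimated correlation). A count adjusted over the list alone gave 3 higher and 1, Prph, lower (log2 difference -3.47, adjusted p = 0.172 over all genes, 5 of 5 pairs). Chat, which makes acetylcholine, was at 45.7 ± 38.0 against 0.376 ± 0.592 TPM, a log2 difference of 3.79 ± 0.68 (adjusted p = 0.00421, 5 of 5 pairs). The choline transporter Slc5a7 had a log2 difference of 3.86 ± 0.71 (adjusted p = 0.00484, 4 of 5 pairs). Slc18a3, the vesicular acetylcholine transporter (3.86 ± 0.84, adjusted p = 0.0223, 5 of 5 pairs), lies within Chat, so TPM cannot separate them with certainty. Among neuropeptides, 1 of 17 was higher and 3 lower (camera adjusted p = 0.806), and adjusted over the list alone 1 was higher and 4 lower. Among hindbrain transcription factors, 2 of 14 were higher and 1, Atoh1, lower (camera adjusted p = 0.548). The higher ones were Tfap2b (log2 difference 4.87 ± 0.60, adjusted p = 8.39e-05) and Meis2 (5.53 ± 0.86, adjusted p = 0.00107), each in 5 of 5 pairs.

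Among the largest positive differences outside the lists were Crabp1, which binds retinoic acid (log2 difference 9.56 ± 1.01, adjusted p = 1.11e-05), the Notch ligand gene Dlk1 (7.12 ± 0.92, adjusted p = 0.000166), Arhgap36 (6.72 ± 0.98, adjusted p = 0.000575) and Serpinf1 (6.21 ± 1.11, adjusted p = 0.00396), each in 5 of 5 pairs. Lower in 5 of 5 pairs were Tmem114 (log2 difference -7.02, adjusted p = 0.00056), the synaptic vesicle gene Synpr (-6.75, adjusted p = 0.000177), the Wnt modulator Sfrp2 (-6.74, adjusted p = 5.47e-06) and the transcription factor Scx (-6.16, adjusted p = 0.00352). Tmem163 (-6.06, adjusted p = 1.17e-05) and the sulfotransferase Hs3st1 (-5.58, adjusted p = 0.00361) followed, also in 5 of 5 pairs. Htr2c, a serotonin receptor, was at 0.143 ± 0.249 against 49.2 ± 36.5 TPM, a log2 difference of -5.11 ± 0.73 (adjusted p = 0.000456, 5 of 5 pairs).

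Among immature neuron genes, the growth cone gene Gap43 (log2 difference 1.13 ± 0.18, adjusted p = 0.0011, 5 of 5 pairs) and Stmn1 (1.09 ± 0.24, adjusted p = 0.0231, 4 of 5 pairs) were higher, and Marcksl1 (-3.68 ± 0.74, adjusted p = 0.013, 5 of 5 pairs) was lower. The list did not pass (camera adjusted p = 0.362), with 4 members higher and 3 lower adjusted over the list alone. Of the MHC class I and interferon response genes, Ifi27 (log2 difference -4.71 ± 1.00, adjusted p = 0.0192) and B2m (-4.18 ± 0.90, adjusted p = 0.0205) were lower, each in 4 of 5 pairs, and the list did not pass (camera adjusted p = 0.387). Markers of microglia stood below 0 in 11 of 11 members (camera adjusted p = 0.184) and of oligodendrocytes in 9 of 10 (camera adjusted p = 0.704). C1qb of microglia was at 2.88 ± 4.09 against 58.0 ± 41.9 TPM. Of the mitochondrially encoded genes, 9 of 13 lay above 0 (camera adjusted p = 0.00785), with adjusted p = 0.873 with an estimated correlation. The cytosolic ribosomal proteins had a median log2 difference of 0.05 and a mean of -0.02 while the test pointed up (camera adjusted p = 0.000864), with adjusted p = 0.873 with an estimated correlation. The 1 OPC gene tested, C1ql1 (log2 difference 4.06 ± 1.12, adjusted p = 0.0893, 5 of 5 pairs), gave camera adjusted p = 0.00785, and adjusted p = 0.0719 with an estimated correlation. Adjusted camera p of the other lists lay between 0.0707 for serotonin receptors and 0.975 for astrocyte markers. The count of genes was 44 (26 higher, 18 lower) without the batch 5 P9 set, 71 without the batch 4 wild-type P94 set and 347 (32 higher, 315 lower) in wild-type sets alone. With genes detected as a covariate it was 52 (29 higher, 23 lower) and without cells under 7000 genes 49 (26 higher, 23 lower), so neither kept the excess of lower genes. The limit of 7000 genes left 3 pairs, all of batch 4. The excess was also absent with a pseudocount of 10 (69 higher, 68 lower) and with only the 2 types in the model (34 higher, 27 lower). Among C1 cells complexity was mixed with genotype. Wild-type ones averaged 5461.8 (young) and 7355 (adult) genes detected, against 10113.5 in P94 double-knockout cells and 10323 in the 1 Gpr4-knockout cell. The 347 genes in wild-type sets therefore rest on the C1 libraries with the fewest genes detected. The median log2 difference of all genes was -1.18 in that fit.

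**Figure D1:**
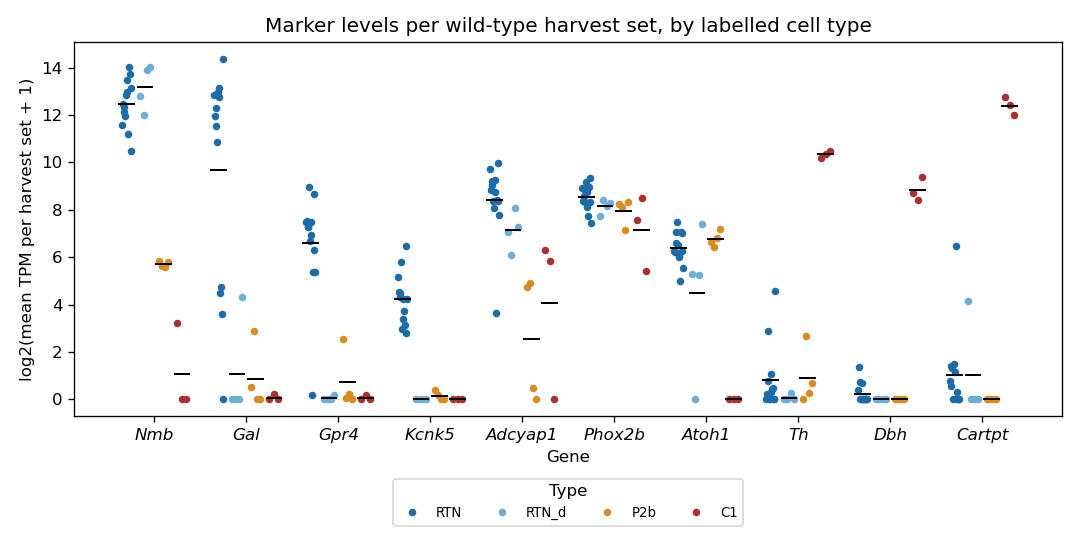
Expression of marker genes by labelled cell type in wild-type cells, as log2 of the mean TPM per harvest set plus 1. Points are harvest sets (13 RTN, 4 RTN_d, 4 P2b, 3 C1) and bars are means; Th, Dbh and Cartpt stand high in C1 sets, and Gpr4 and Kcnk5 in RTN sets.

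P2b neurons are further fluorescent neurons of the same harvest sets, and this comparison asked what sets RTN neurons apart from them. P2b neurons held Nmb in all 10 cells, at 51.6 ± 4.10 TPM against 5118 ± 4575 in RTN neurons of the same sets (SD, n = 4 sets each). Adcyap1, Kcnk5 and Phox2a were lower in P2b neurons. The calcium sensor Hpca, the cadherin Cdh8 and Reln, which encodes a secreted protein of neuronal migration, were higher. In limma, 19 genes passed the threshold, 7 higher and 12 lower, all in 4 of 4 pairs. That balance was not stable, with 18 higher and 9 lower with a pseudocount of 10, 3 and 11 with a pseudocount of 0.1, and 36 and 37 with sets weighted by cells. The median log2 difference of all genes was -0.14, and genes detected were 9193 ± 1389 against 10270 ± 233 (exact sign-flip p = 0.375, n = 4 pairs, smallest possible 0.125).

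Of 10 RTN markers, 3 were lower over all genes and 6 adjusted over the list alone (camera adjusted p = 1.24e-12, and adjusted p = 0.00312 with an estimated correlation). Nmb had a log2 difference of -6.18 ± 0.58 (adjusted p = 9.29e-06, 4 of 4 pairs) and passed in 21 of 21 settings tried. Adcyap1 was at 13.8 ± 15.8 against 560 ± 415 TPM, a log2 difference of -5.68 ± 1.03 (adjusted p = 0.0227, 4 of 4 pairs). Kcnk5 was at 0.112 ± 0.143 against 33.0 ± 37.5 TPM, a log2 difference of -3.86 ± 0.75 (adjusted p = 0.0329, 4 of 4 pairs). Gal had a log2 difference of -7.56 ± 1.59 (adjusted p = 0.0649, 4 of 4 pairs), Penk of -5.76 ± 1.35 (adjusted p = 0.116, 3 of 4 pairs) and Gpr4 of -4.76 ± 1.18 (adjusted p = 0.141, 3 of 4 pairs). Atoh1, at 110 ± 26.1 against 80 ± 41.8 TPM (log2 difference -0.30, adjusted p = 0.988), and Phox2b (-0.82, adjusted p = 0.739, 4 of 4 pairs) did not pass. For Atoh1 the mean TPM and the log2 difference had opposite signs, and only 1 of 4 pairs was lower. By cell, Gpr4 was found in 1 of 10 P2b cells, Kcnk5 in 0, Gal in 2, Adcyap1 in 6 and Atoh1 in 8.

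Of 17 neuropeptides, 2 were lower over all genes, Nmb and Adcyap1 (camera adjusted p = 4.03e-05, and adjusted p = 0.0103 with an estimated correlation). Adjusted over the list alone 5 were lower and 1 higher, the dynorphin precursor Pdyn at 48.8 ± 37.9 against 2.86 ± 5.72 TPM (log2 difference 4.10 ± 0.89, adjusted p = 0.0719 over all genes, 4 of 4 pairs). Of 24 immature neuron genes, 19 lay above 0, and the list was higher (camera adjusted p = 1.98e-08, and adjusted p = 0.0408 with an estimated correlation). Tmsb10, which binds actin monomers, was the 1 member past the threshold over all genes, at 3964 ± 538 against 2048 ± 634 TPM (log2 difference 1.01 ± 0.17, adjusted p = 0.0218, 4 of 4 pairs). Adjusted over the list alone 6 were higher, including Tuba1a (log2 difference 0.72, adjusted p = 0.0993, 4 of 4 pairs) and Stmn1 (0.76, adjusted p = 0.498, 4 of 4 pairs). Among adrenergic C1 markers, Phox2a was lower, listed at 0 in P2b against 60.2 ± 33.4 TPM (adjusted p = 0.0176, 4 of 4 pairs), and the list did not pass (camera adjusted p = 0.0523).

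Outside the lists, Lypd6b, which belongs to a family of nicotinic receptor modulators, was at 93.3 ± 84.2 against 1.67 ± 3.34 TPM (log2 difference 5.41 ± 0.90, adjusted p = 0.0176). Hpca was at 447 ± 184 against 67.0 ± 62.3 TPM (3.79 ± 0.66, adjusted p = 0.0218). Cdh8 (log2 difference 4.52 ± 0.84, adjusted p = 0.0246), Reln (4.23 ± 0.79, adjusted p = 0.0246) and Arhgef3 (4.10 ± 0.81, adjusted p = 0.0334) were the other named higher genes. Lower were Csgalnact1 (log2 difference -4.86 ± 0.92, adjusted p = 0.029), the transcription factor Etv5 (-4.85 ± 0.88, adjusted p = 0.0227), C1ql3 (-4.83 ± 0.94, adjusted p = 0.0329) and Ergic1 (-4.34 ± 0.85, adjusted p = 0.0329). The immediate early phosphatase gene Dusp1 was at 35.2 ± 58.4 against 184 ± 89.9 TPM (-4.75 ± 0.87, adjusted p = 0.0227). All of these differed the same way in 4 of 4 pairs.

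Further lists passed with the preset correlation alone. Mitochondrially encoded genes lay above 0 in 13 of 13 members (camera adjusted p = 1.96e-07), with adjusted p = 0.324 with an estimated correlation. In 1 of the 2 P2b cells of the batch 5 P11 set these genes took 25.69% of the TPM, against a median of 3.73% in clean cells. The list was not tested without that cell. Mature neuron genes lay above 0 in 19 of 24 (camera adjusted p = 2.42e-05), with adjusted p = 0.248 with an estimated correlation, and adjusted over the list alone the neurofilament genes Nefh, Nefm and Nefl were higher and Spock3 lower. Immediate early and stress genes lay below 0 in 13 of 15 (camera adjusted p = 0.000286), with adjusted p = 0.248 with an estimated correlation. Synaptic vesicle genes lay above 0 in 12 of 21 (0.00423, and adjusted p = 0.408 with an estimated correlation), and perineuronal net genes in 4 of 4 (0.0151, and adjusted p = 0.152 with an estimated correlation). Proton and CO2 sensing candidates lay below 0 in 7 of 9 (0.018, and adjusted p = 0.128 with an estimated correlation), and peptide, opioid and purine receptors in 12 of 13 (0.0452, and adjusted p = 0.248 with an estimated correlation). Markers of oligodendrocytes lay below 0 in 10 of 10 members (camera adjusted p = 0.0734), and Mbp was at 1722 ± 1090 against 2865 ± 1356 TPM. Adjusted camera p of the remaining lists lay between 0.0523 and 0.889. The count of genes was 1 with only the 2 types in the model and 3 without any 1 of the batch 3 P12, batch 5 P9 and batch 5 P8 sets, and 11 without the batch 5 P11 set.

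RTN_d neurons carry a label whose letter is not explained, and the comparison asked where they stand beside RTN neurons. They held Nmb at 10730 ± 6089 against 7961 ± 7297 TPM in RTN neurons of the same sets (SD, n = 4 sets each, log2 difference 1.38 ± 0.58, adjusted p = 0.785, 3 of 4 pairs). None of the 5 RTN_d cells held Gpr4 or Kcnk5 at TPM of at least 1, and 1 held Gal. Over all genes none passed the threshold in limma, with 671 at an unadjusted p under 0.05 and a smallest adjusted p of 0.18. Adjusted over the list alone, 3 of 10 RTN markers were lower: Gpr4 at 0.0325 ± 0.065 against 141 ± 181 TPM (log2 difference -4.84 ± 1.18, adjusted p = 0.508 over all genes, 4 of 4 pairs), Kcnk5 listed at 0 against 29.5 ± 39.4 TPM (adjusted p = 0.18 over all genes, 4 of 4 pairs) and Gal (-6.13 ± 1.59, adjusted p = 0.6 over all genes, 4 of 4 pairs).

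Within their lists alone, the neuropeptide gene Pdyn (log2 difference 2.98 ± 0.89, adjusted p = 0.644 over all genes, 3 of 4 pairs) and the serotonin receptor gene Htr1b (2.46 ± 0.78, adjusted p = 0.659, 4 of 4 pairs) were higher in RTN_d. Phox2b (log2 difference -0.49, adjusted p = 0.908, 3 of 4 pairs), Adcyap1 (-0.25, adjusted p = 0.984, 3 of 4 pairs) and Penk (-3.31, adjusted p = 0.785, 3 of 4 pairs) did not pass. With the preset correlation 6 lists passed, and none with an estimated one. RTN markers gave camera adjusted p = 0.0154 (adjusted p = 0.459 with an estimated correlation) and proton and CO2 sensing candidates 0.0205 (adjusted p = 0.397 with an estimated correlation). Mature neuron genes gave 0.0227, cytosolic ribosomal proteins 4.67e-06, mitochondrially encoded genes 2.63e-05 and nuclear oxidative phosphorylation genes 0.000299, each with adjusted p = 0.653 with an estimated correlation. They lay above 0 in 21 of 24, 59 of 73, 13 of 13 and 60 of 72 members. Genes detected were 9194 ± 1089 against 9879 ± 987 (exact sign-flip p = 0.25, n = 4 pairs, smallest possible 0.125).

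Adult RTN neurons (P48 to P118, 5 sets) were compared with young ones (P5 to P13, 8 sets) to ask what differs with age. No gene passed the threshold in limma, with 606 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0571. Nmb was at 9310 ± 5570 TPM in adult and 5690 ± 3481 TPM in young sets (SD). It was the 1 RTN marker higher in adults when adjusted over the list alone (log2 difference 1.44 ± 0.35, adjusted p = 0.268 over all genes, 3 of 3 batches). Gpr4 (log2 difference 0.16 ± 1.09, adjusted p = 0.983, 2 of 3 batches), whose sign turned under several alternatives, Kcnk5 (-0.90 ± 0.99, adjusted p = 0.917, 1 of 3 batches) and Phox2b (0.07 ± 0.36, adjusted p = 0.975, 1 of 3 batches), whose sign turned too, did not pass. Adult libraries held 8441 ± 1221 genes detected against 10081 ± 642 (exact permutation p = 0.00544, n = 5 and 8 sets, smallest possible 0.000777), and the median log2 difference of all genes was -0.33. That permutation ignored batch, and batches 1 and 2 held young sets only. Within batches, adult sets averaged 8085 genes detected against 9974 in batch 3, 9284 against 9185 in batch 4 and 8375 against 10054 in batch 5. The batch 3 adult value averages 2 sets, and 1 of them, P48, is a single cell with 6506 genes detected. With stage permuted within batches, a test chosen after seeing the data, the difference did not pass, whether batches were weighted as in a fit with batch as a term (exact permutation p = 0.0889) or equally (exact permutation p = 0.156, smallest possible 0.0111 for both).

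Immature neuron genes lay below 0 in 23 of 24 members (camera adjusted p = 2.67e-05), with adjusted p = 0.141 with an estimated correlation, and 3 were lower adjusted over the list alone. These were Marcksl1 at 114 ± 69.9 against 318 ± 100 TPM (log2 difference -3.31 ± 0.54, adjusted p = 0.0571 over all genes, 3 of 3 batches), Nnat (-2.63 ± 0.54, adjusted p = 0.142, 3 of 3 batches) and Tuba1a (-0.94 ± 0.21, adjusted p = 0.233, 3 of 3 batches). Synaptic vesicle genes lay above 0 in 16 of 19 (camera adjusted p = 1.1e-06), with adjusted p = 0.141 with an estimated correlation. Mature neuron genes lay above 0 in 16 of 24 (camera adjusted p = 2.67e-05), with adjusted p = 0.16 with an estimated correlation. Snap25 had a log2 difference of 0.90 ± 0.30 (adjusted p = 0.763, 3 of 3 batches) and Cplx1, a regulator of vesicle release, of 0.85 ± 0.27 (adjusted p = 0.741, 3 of 3 batches). Perineuronal net genes lay above 0 in 4 of 4 (camera adjusted p = 0.0353), with adjusted p = 0.242 with an estimated correlation. Immediate early and stress genes lay below 0 in 13 of 15 (camera adjusted p = 0.00197), with adjusted p = 0.362 with an estimated correlation. Fos, lower adjusted over the list alone, was at 117.8 ± 50 against 387 ± 120 TPM (log2 difference -2.57 ± 0.47, adjusted p = 0.135 over all genes, 3 of 3 batches).

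Of the markers of other cells, 3 lists lay lower in adult sets with the preset correlation alone, while astrocyte markers (camera adjusted p = 0.126), the 1 OPC marker (0.27) and vascular markers (0.936) did not pass. Red blood cell genes lay below 0 in 4 of 4 members (camera adjusted p = 1.1e-06), with adjusted p = 0.177 with an estimated correlation, and Hba-a2 was at 2.85 ± 3.93 against 203 ± 222 TPM (log2 difference -5.23 ± 1.03, adjusted p = 0.142, 3 of 3 batches). Microglia markers lay below 0 in 10 of 11 (camera adjusted p = 0.000354), with adjusted p = 0.362 with an estimated correlation, and 5 were lower adjusted over the list alone, among them Tyrobp at 12.3 ± 17.9 against 151 ± 147 TPM. Oligodendrocyte markers lay below 0 in 12 of 12 (camera adjusted p = 0.00472), with adjusted p = 0.464 with an estimated correlation, and Mbp was at 579 ± 537 against 2990 ± 1490 TPM (log2 difference -2.85 ± 0.58, adjusted p = 0.142, 3 of 3 batches). Mitochondrially encoded genes lay below 0 in 12 of 13 (0.00061, and adjusted p = 0.464 with an estimated correlation). Ribosomal proteins lay above 0 in 44 of 73 (0.000318) and nuclear oxidative phosphorylation genes in 43 of 72 (0.000217), each with adjusted p = 0.66 with an estimated correlation. The count of genes was 140 with sets weighted by their cells, 31 with sets of the same age merged and 22 without the batch term.

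**Figure D2:**
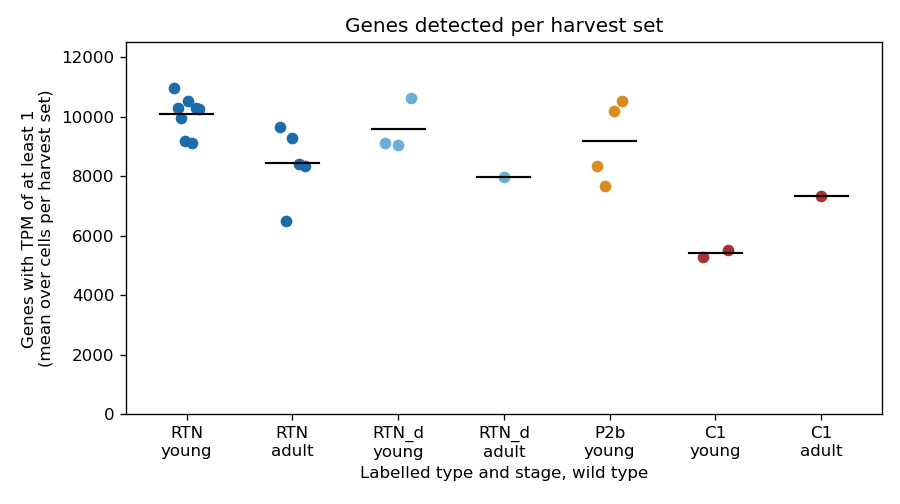
Genes with TPM of at least 1, mean over cells per wild-type harvest set, by labelled cell type and stage. Points are harvest sets (RTN 8 young and 5 adult, RTN_d 3 and 1, P2b 4 young, C1 2 and 1) and adult RTN sets average 8441 genes against 10081 in young ones.

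The knockouts served to ask whether loss of the proposed proton detectors Gpr4 and TASK-2 altered RTN neurons. Gpr4 RNA was at 6.80 ± 1.17 TPM in the 3 Gpr4-null sets and 164 ± 142 TPM in the 13 wild-type sets (SD, exact permutation p = 0.0107, smallest possible 0.00179). The permutations of Gpr4 and Kcnk5 given here used set means of log2(TPM + 1) and ignored batch. The null sets stood at 5.45 TPM (P94 double knockout), 7.37 TPM (P14 double knockout) and 7.57 TPM (P16 Gpr4 knockout). All null sets were in batch 4, whose wild-type sets held 102 TPM at P5 and 179 TPM at P94. The batch 5 P11 wild-type set, which has 1 RTN cell, was at 0.13 TPM. Kcnk5 was at 3.75 and 2.55 TPM in the 2 double-knockout sets against 23.8 ± 22.7 TPM in the 14 others (exact permutation p = 0.0833, smallest possible 0.00833), with 6.80 and 17.6 TPM in the batch 4 wild-type sets and 13.4 TPM in the Gpr4 knockout set.

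Over all genes none passed the threshold in limma, with 77 at an unadjusted p under 0.05 and a smallest adjusted p of 1. Gpr4 had a log2 difference of -3.44 ± 1.54 (adjusted p = 1, 3 of 3 null sets) and Kcnk5 of -0.60 ± 1.34 (adjusted p = 1, 2 of 3 null sets). Nmb (0.43 ± 0.55), Phox2b (-0.50 ± 0.50) and Gal (-2.38 ± 2.62) did not pass, and the sign of Nmb turned without the P14 double-knockout set and that of Kcnk5 without the batch 4 wild-type P94 set. RTN markers gave camera adjusted p = 0.0852. Gad1 was at 20.4 ± 17.0 TPM in null and 3.41 ± 2.79 TPM in wild-type sets (log2 difference 1.84 ± 1.22) and Slc32a1 at 7.10 ± 3.98 and 1.12 ± 1.39 TPM (1.54 ± 0.82), with camera adjusted p = 0.0586 for GABA and glycine markers. These values leave out 7 RTN cells labelled GAD contaminated, with Gad1 from 31.4 to 246 TPM, all of them wild type. No null cell had the label, although 4 held Gad1 at or above 31.4 TPM, so the label trimmed the wild-type sets alone on the genes compared. With the labelled cells put back, wild-type sets held Gad1 at 16.0 ± 27.2 TPM and Slc32a1 at 2.93 ± 4.83 TPM, and the log2 difference of Gad1 was 1.29. Genes detected were 9598 ± 1425 in null and 9450 ± 1195 in wild-type sets (exact permutation p = 0.875).

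With the preset correlation 7 lists passed, none with an estimated one. Mature neuron genes lay above 0 in 20 of 25 members (camera adjusted p = 1.22e-11), with adjusted p = 0.122 with an estimated correlation, and Pvalb, a calcium-binding protein gene, had a log2 difference of 4.80 ± 1.61. Immature neuron genes lay below 0 in 21 of 24 (4.32e-07), with adjusted p = 0.122 with an estimated correlation. Synaptic vesicle genes lay above 0 in 15 of 19 (0.000474, and adjusted p = 0.215 with an estimated correlation). Ribosomal proteins lay below 0 in 64 of 73 (6.59e-11, and adjusted p = 0.423 with an estimated correlation) and sex-linked genes above 0 in 4 of 4 (0.0359, and adjusted p = 0.32 with an estimated correlation). Beside these, oligodendrocyte markers lay above 0 in 12 of 12 (3.93e-10, and adjusted p = 0.194 with an estimated correlation), with a log2 difference of 3.44 ± 1.29 for Cldn11 and 2.44 ± 1.01 for Mbp. Astrocyte markers lay above 0 in 7 of 9 (0.00329, and adjusted p = 0.215 with an estimated correlation), with 2.40 ± 1.27 for S100b. Age is mixed with genotype here, since the young null sets were P14 and P16 and the 1 young wild-type set of batch 4 was P5. Sex may be mixed in too. RNA of the Y-linked gene Eif2s3y reached TPM of 10 in most P14 and P16 null cells and in few P5 cells. It did so in no P94 cell of either genotype in that batch. As list medians relative to all genes, chosen after seeing the data, immature neuron genes were at -1.14 in the P14 and P16 null sets against P5 but at 0.35 in null against wild type at P94, and synaptic vesicle genes at 0.66 and -0.15. Mature neuron genes (1.25 and 0.88), oligodendrocyte markers (1.69 and 2.88), astrocyte markers (0.43 and 1.82) and ribosomal proteins (-0.61 and -0.18) kept their sign at P94, with 1 set on each side. The count of genes was 39 without the filter, 27 with sets weighted by cells, 8 with ages merged and 7 without the batch term.

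In batch 4 at P94, 1 double-knockout set of 4 cells can be set beside 1 wild-type set of 5 cells, without a test. Gpr4 was at 5.45 against 179 TPM, Kcnk5 at 3.75 against 17.6, Nmb at 9130 against 8050, Phox2b at 371 against 430 and Adcyap1 at 395 against 430 TPM. Gal was at 139 against 6910 TPM, with single wild-type cells from 0 to 19400. Gad1 was at 35.2 against 5.03, Gad2 at 11.0 against 0.14 and the glycine transporter Slc6a5 at 5.49 against 1.07 TPM. The wild-type values leave out 1 labelled cell with Gad1 at 246 TPM, and with it the wild-type set held Gad1 at 45.3 TPM, above the double knockout, Gad2 at 4.66 and Slc6a5 at 0.973 TPM. The myelin genes Mbp at 3410 against 493 TPM and Plp1 at 274 against 36.6 TPM also stood higher in the double-knockout set.

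**Figure D3:**
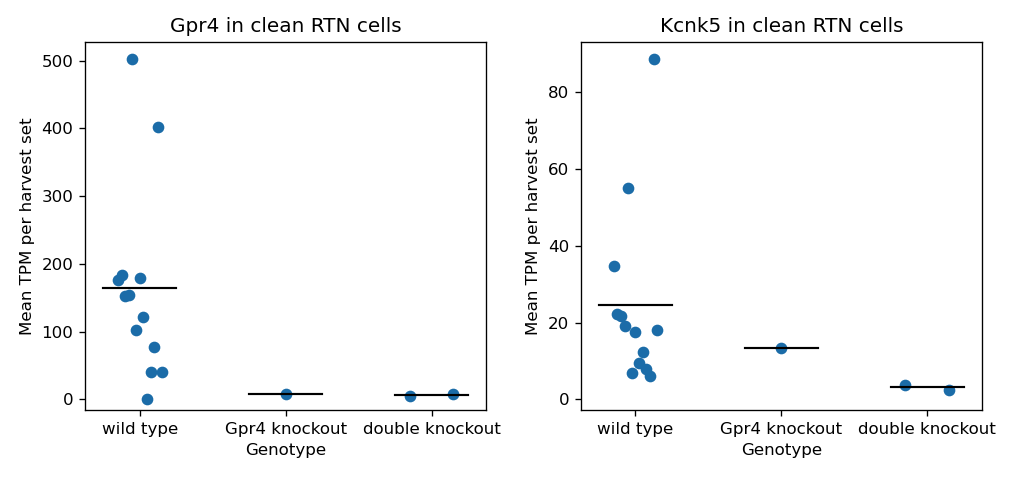
Mean TPM of Gpr4 and Kcnk5 per harvest set in clean RTN cells, by genotype. Points are harvest sets (13 wild type, 1 Gpr4 knockout, 2 double knockout) and bars are means, with Gpr4 between 5.45 and 7.57 TPM in the null sets.

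Cells labelled GAD contaminated, 1 in each of 7 sets, were set beside clean RTN cells of the same sets, to ask what else came with the label. GAD stands for the GABA-synthesis enzymes, so the label was most likely given from these genes, and they are not independent evidence. Over all genes none passed the threshold in limma, with 693 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0944. That was Gad1, at 95.8 ± 88.0 against 4.13 ± 2.41 TPM (SD, n = 7 sets, log2 difference 4.63 ± 0.70, adjusted p = 0.0944, 7 of 7 pairs). Adjusted over the list alone, 4 of 6 GABA and glycine markers were higher, Gad1, Gad2 at 11.0 ± 8.43 against 1.02 ± 0.890 TPM, Slc32a1 at 13.5 ± 16.0 against 1.55 ± 1.76 TPM and Lhx1 (camera adjusted p = 1.73e-05), with adjusted p = 0.179 with an estimated correlation.

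RTN markers lay below 0 in 10 of 10 members (camera adjusted p = 0.000216), with adjusted p = 0.383 with an estimated correlation. Nmb was at 2351 ± 1210 against 6926 ± 4589 TPM (log2 difference -1.03 ± 0.41, adjusted p = 0.78, 6 of 7 pairs), and the sign of Gpr4 (-0.56 ± 0.72) and of Kcnk5 (-0.40 ± 0.79) turned without the batch 4 P94 set. Neuropeptides lay below 0 in 10 of 14 (0.00467, and adjusted p = 0.187 with an estimated correlation). Astrocyte markers lay above 0 in 11 of 11 (0.00467, and adjusted p = 0.608 with an estimated correlation), microglia markers in 10 of 11 (0.0365, and adjusted p = 0.903 with an estimated correlation) and red blood cell genes in 4 of 4 (0.000426, and adjusted p = 0.565 with an estimated correlation). Hba-a2 was at 498 ± 944 against 77.4 ± 131 TPM. Ribosomal proteins lay above 0 in 62 of 73 (0.000146, and adjusted p = 0.903 with an estimated correlation). Genes detected were 10268 ± 1286 against 9141 ± 1402 (exact sign-flip p = 0.0938, n = 7 pairs, smallest possible 0.0156), and the median log2 difference of all genes was 0.19. Without the batch 3 P12 set, 3 genes passed.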

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

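The share of lower genes among those past the threshold in C1 neurons and the Gad1 level of double-knockout C1 cells were tests chosen only after the result was seen, and the complexity covariate, the limit of 7000 genes detected and the levels with labelled cells put back were chosen after seeing the data.

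More genes were lower than higher in C1 neurons, 63.6% of those past the threshold, but not with a pseudocount of 10 (69 higher, 68 lower), with only the 2 types in the model (34 higher, 27 lower) or without the batch 5 P9 set (26 higher, 18 lower). With genes detected as a covariate the lower share was 44.2%, without cells under 7000 genes detected it was 46.9%, and the median of all genes moved from -0.60 to 0 and 0.05, so lower complexity may contribute to an excess that also depends on the pseudocount, the model and 1 set. The limit of 7000 genes left 3 pairs, all of batch 4, and no young wild-type C1 cell. Its effect is therefore mixed with that loss. Complexity was also mixed with genotype, as wild-type C1 libraries had fewer genes detected than those of the knockouts. The 84 genes called lower had a median of -3.33 with the covariate and -3.43 without cells under 7000 genes, from -3.92, and all 84 stayed below 0. They were chosen as lower in these same profiles and were therefore likely to stay below 0. Their medians do not decide whether complexity is a cause. Only 23 lower genes passed the threshold in each of these 2 fits. Of 100 splits of the 10 profiles, which do not keep the pairs, 4 gave at least the real 132 genes. The highest others gave 663 and 449, and what raised these counts was not tested. The split with 663 put 4 of the 5 C1 profiles in the arm with 7292 genes detected against 9807. Those with 449 kept both profiles of 4 sets in 1 arm. The splits that part every pair number 16, too few for a share under 0.05, with 1 at the real count and a highest other of 0.

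Immature neuron genes lay lower in adult RTN neurons, by -0.42 as a list median relative to all genes, beside fewer genes detected. The list passed with the preset correlation alone, as did the red blood cell, microglia and oligodendrocyte lists, which also lay lower. With genes detected as a covariate the value was -0.71, and between -0.84 and -0.39 without any 1 set, which argues against complexity as the whole cause. The fit had batch as a term, but within batches the value was 0.11 in batch 3, -1.36 in batch 4 and -0.32 in batch 5. The 1 young set of batch 4 was P5, while those of batches 3 and 5 were P12 and P8 to P13. Batch is thus mixed with the age of the young sets, and an effect that differs by either stays open. The real count of single genes was 0, which all 100 splits must reach (highest other 69), so the splits test nothing here. Age itself may be the cause and was not tested apart from RNA of other cells.

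GABA and glycine markers stood at a mean log2 level of 2.34 and 2.00 in the 2 double-knockout sets against 0.75 to 0.94 in the other batch 4 sets, from which the label GAD contaminated had removed 2 cells, both wild type. With these put back the other sets stood at 0.75 to 1.06, but mean Gad1 at P94 turned to 35.2 TPM in the double knockout against 45.3 TPM in wild type. RNA from other cells may contribute, as 2 of 3 lists of other cells were higher in both sets than in every other batch 4 set: astrocyte markers at 4.77 and 3.55 and oligodendrocyte markers at 5.49 and 4.84, while microglia markers, at 1.64 and 3.21, were not, which leaves this source open. Gad1 was also present in the C1 cells of the P94 double-knockout set, at 18.5 and 20.2 TPM against 0 in both wild-type C1 cells of that age and batch. It was therefore not confined to the RTN cells of that set. GAD RNA in the harvest and a genotype effect on both cell types would each give this, so it does not decide between them. The double-knockout C1 cells also had more genes detected, 9641 and 10586 against 8662 and 6048. An effect of the genotype was not tested apart from the harvest, since each double-knockout set is 1 batch, age and genotype.

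Single sets stood far from the others of their group in 21 of 134 groups of 4 to 10 sets, where chance gives about 1 in 20 for values away from the floor. Where all other sets lie at 0 the value is 1 by construction, so no excess over chance is shown. Each value below is the gap to the nearest other set as a share of the group's range, beside levels in log2(TPM + 1). In C1 sets it was 1 for 5 genes that 1 set alone held: Tmem114 (2.67), Sfrp2 (1.06) and Scx (2.16) in the P94 double-knockout set, Synpr (0.14) in the batch 5 P13 set and Gal (0.20) in the batch 5 P9 set. In RTN sets of that comparison, Serpinf1 gave 0.746 (4.29 in the batch 5 P13 set, at most 1.09 elsewhere) and Atoh1 0.757 (6.98 in the P94 double-knockout set, 5.53 to 5.88 elsewhere). In P2b sets, Csgalnact1 (0.79) and Etv5 (0.60) gave 1 in the batch 5 P9 set, Gpr4 gave 0.862 (1.72 in the batch 3 P12 set, at most 0.24 elsewhere) and Phox2b 0.866 (6.59 in the batch 5 P11 set, 8.10 to 8.33 elsewhere). In their RTN sets, Lypd6b gave 1 (1.08 in the batch 3 P12 set, 0 elsewhere) and Kcnk5 0.877 (6.49 in the batch 5 P8 set, 3.34 to 3.72 elsewhere). In RTN_d sets, Gal (4.31) and Gpr4 (0.18) in the batch 5 P9 set and Th (0.29) in the batch 5 P8 set gave 1. In their RTN sets, genes detected gave 0.873 (8410 in the batch 5 P80 set, 10274 to 10545 elsewhere). Among young sets, the batch 5 P11 set gave 0.612 for Gpr4 (0.18, 5.37 to 8.65 elsewhere) and 0.634 for Adcyap1 (3.65, 7.67 to 10 elsewhere). Among contaminated cells, Gpr4 gave 0.77 (0 in the batch 4 P94 set, 5.97 to 7.75 elsewhere), and among the clean cells of these sets Gad1 gave 0.592 (0 in the batch 3 P48 set, 1.40 to 2.36 elsewhere).

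Most libraries described here, all outside the comparisons, held signals above the range of single clean cells of their type. The 2 pooled RTN libraries had 13377 and 13264 genes detected, above the 5174 to 12600 of 91 single RTN cells, and 1 of them held Gad1 at 168 TPM (at most 62.6 in single cells). The contaminated RTN_d cell held Gad1 at 39.6 TPM (at most 10.2). The 2 contaminated P2b cells held Gad2 at 34.0 and 43.4 TPM (at most 2.62) and Th at 84.6 and 36.7 TPM (at most 27.1), and 1 of them held Nmb at 505 TPM (at most 146). The P2b cell labelled as bad data held 10137 genes detected, within the 5791 to 11662 of clean young P2b cells, and mitochondrially encoded genes took 1.1% of its TPM (1.1% to 25.7% in clean young P2b cells).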

How the results depend on the processing

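The complexity covariate and the limit on genes detected were alternatives chosen only after the result was seen; the others were planned. TPM hold no depth, so what depth limits could not be measured. Of 1448 values of named genes under alternatives, 1274 kept their direction and side of the threshold, 130 kept the direction and lost the call, 16 gained one and 28 turned sign. Upper-quartile scaling moved the median of all genes from -0.60 to -0.78 for C1, from -0.33 to -0.51 for age and from 0.19 to 0.40 for contaminated cells, so list results are relative to all genes. Where a set left out leaves few in an arm, its spread is taken from the whole fit. The cause was not tested for any change below, except that fewer sets, profiles or tested genes enter where sets or types are left out or filters change.

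For C1, 132 genes became 48 without a filter, 286 with weights by cells, 61 with only the 2 types, 347 in wild-type sets, 49 without cells under 7000 genes (42 shared, 3 pairs left) and 52 with the covariate (all 52 shared). Leaving out 1 set gave 44 (batch 5 P9) to 150 (P16 Gpr4 knockout), with 71 without the wild-type P94 set. For P2b, 19 (7 higher, 12 lower) became 27 (18 higher, 9 lower) with pseudocount 10, 14 (3 higher, 11 lower) with pseudocount 0.1, 6 without a filter, 73 (36 higher, 37 lower) with weights, 1 with only the 2 types and 29 without cells under 7000 genes, and leaving out 1 set gave 3 (batch 3 P12, batch 5 P8 or P9) to 26 (batch 5 P13), with 11 without batch 5 P11. With no replicate block, so that the paired sets were not matched, counts were 232 for C1 (123 shared), 55 for P2b (19 shared), 5 for RTN_d and 1 for contaminated cells. For age, 0 became 2 with a stricter filter, 2 with upper-quartile scaling, 140 with weights, 22 without batch, 31 with ages merged, 2 with sets of at least 2 cells and 3 with contaminated cells included; without 1 set it was 0 to 3 (3 without batch 3 P12 or P118, 1 without batch 3 P48 or batch 5 P80). For genotype, 0 became 39 without a filter, 27 with weights, 7 without batch and 8 with ages merged, and stayed 0 without each set. For RTN_d leaving out 1 set gave 0 each time, and for contaminated cells 0 to 3 (3 without batch 3 P12). Lists past the threshold went with an estimated correlation from 6 to 3 (C1), 10 to 3 (P2b), 6 to 0 (RTN_d), 11 to 0 (age), 7 to 0 (genotype) and 7 to 0 (contaminated). The difference in genes detected of null sets, 147, was -192 at TPM above 0 and -158 at TPM of at least 10.

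Signs turned for genes that did not pass. For C1, Gad1 (-0.39) was 0.01 with only the 2 types and 0.26 with the covariate. For P2b, Th (0.03) was -0.02 with pseudocount 0.1, -0.01 with weights, -0.53 with no block and -0.13 (without batch 5 P8) to 0.13 without 1 set, and Gad1 (-0.45) was 0.07 with weights and -1.17 to 0.17 (without batch 5 P11) without 1 set. For RTN_d, Gad1 (0.66) was -0.35 (without batch 5 P9) to 1.47. For age, Gpr4 (0.16) was -0.13 with upper-quartile scaling, -0.60 with ages merged, -0.64 with at least 2 cells, -0.67 without cells under 7000 genes, -0.72 with the covariate, and -0.66 (without batch 5 P11) to 0.77 without 1 set, with -0.38 without batch 3 P12 and -0.15 without batch 3 P48. Phox2b (0.07) was -0.27 with upper-quartile scaling, -0.16 with weights, -0.13 with ages merged, -0.06 with contaminated cells, and -0.17 (without batch 5 P80) to 0.25 without 1 set, with -0.02 without batch 5 P11 and -0.07 without batch 5 P13. For genotype, Kcnk5 (-0.60) was -1.78 to 0.45 (without the wild-type P94 set) and Nmb (0.43) was -0.07 (without the P14 double knockout) to 0.80. For contaminated cells, Gpr4 (-0.56) was -1 to 0.31 and Kcnk5 (-0.40) was -0.96 to 0.03, each highest without batch 4 P94.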

Other observations

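The relation of Nmb to Gal was a test chosen only after the result was seen. Among wild-type cells with a label, the receptor gene Tacr1 was found at TPM of at least 1 in 66 of 73 RTN, 2 of 6 C1, 3 of 10 P2b and 5 of 5 RTN_d cells. Atoh1 was found in 72 RTN, 0 C1, 8 P2b and 4 RTN_d cells, and Adcyap1 in 73, 3, 6 and 5. Penk was found in 70 RTN, 4 C1, 4 P2b and 4 RTN_d cells. Th was found in 6 RTN, 6 C1, 1 P2b and 0 RTN_d cells. At TPM of at least 10, 6678 genes were found in at least 50% of wild-type RTN cells.

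Within RTN neurons of 1 harvest set, Nmb and Gal may fall on opposite sides. The mean within-set Spearman correlation over 8 sets with at least 5 cells (76 cells) was -0.47, below 0 in 7 sets, with a range from -0.97 to 0.10 (exact sign-flip p = 0.0156). These are 6 wild-type sets, the P14 double-knockout set and the P16 Gpr4-knockout set. In the 6 wild-type sets alone (62 cells) it was -0.41, below 0 in 5 sets, and did not pass (exact sign-flip p = 0.0625, smallest possible 0.0312). Adjusted over the 15 pairs of 6 markers in the 8 sets the p was 0.078, so the relation failed the correction. The same adjusted p was reached by Nmb with Gpr4 (mean -0.21) and with Adcyap1 (0.39), and by Gal with Gpr4 (0.45). Gpr4 with Kcnk5 (0.31) and with Phox2b (0.27) reached it too. Nmb and Gal therefore do not stand out by p among the 15 pairs. The mean Pearson correlation of log2(TPM + 1) of Nmb and Gal was -0.55 (exact sign-flip p = 0.00781, the smallest possible, not adjusted over the pairs). It was -0.62 after the 2 cells farthest from the median of Nmb were left out in each set. The P94 wild-type and P14 double-knockout sets hold 5 cells each, so few cells remained in them. With genes detected held fixed the mean Spearman correlation of Nmb and Gal was -0.44 (exact sign-flip p = 0.0469, not adjusted over the pairs), little changed from -0.47. As the relation failed the correction, no conclusion on its cause is drawn. Cells of 1 set are not independent animals, and the sets were the unit of the test.

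Other splits of the profiles were counted for the remaining comparisons. For P2b, 1 of 35 splits, the real one, gave as many as 19 genes and the highest other gave 3, in splits that do not keep the pairs. The 8 splits that part every pair are too few for a share under 0.05 (1 at the real count, highest other 0). Where the real count was 0, every split must reach it, so the splits test nothing and only the highest other counts are of use. For RTN_d, these were 6 among 35 splits and 0 among the 8 that part every pair, which are also too few for a share under 0.05. For genotype, the highest other among 100 splits was 39. For contaminated cells, the highest other among 100 splits was 467. In that split 6 of the 7 sets had both profiles in 1 arm, but other splits of that kind gave 8 genes or fewer. What raised the count in that split was not tested. Among the 64 splits that part every pair the highest other was 2.

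A term for a different effect in adult and young sets passed the threshold in limma for 0 genes in C1 neurons (2 adult and 3 young C1 sets, 369 genes at an unadjusted p under 0.05) and for 0 in contaminated cells (4 adult and 3 young sets, 341 genes). With so few sets this does not show that the effects were alike. For RTN_d and Gpr4-null cells, 1 adult set each leaves the question open.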
